A study of Bos indicus x Bos taurus with 20 samples.

How the data were processed

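The study measured polyA RNA of bovine preimplantation embryos (Bos indicus x Bos taurus) by RNA-seq in 20 samples. Per the labels' protocols, zygotes were injected with METTL7A mRNA made in vitro or with vehicle, and whole embryos or isolated cells went straight into cDNA synthesis with the SMART-Seq v4 Ultra Low Input kit, followed by Tn5 tagmentation and Nextera XT library preparation. This protocol does not mark the strand, so a gene and its antisense partner cannot be told apart. Per the submitters' processing notes, the reads were handled with Trim Galore 0.6.10, FastQC, STAR 2.7.11b and Subread 2.0.6, and DESeq2 1.44.0 was used. The genome build and annotation are not given in the sources used here, and no coordinates are reported.

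The deposited values are whole-number read counts per gene, with no normalization, in 2 tables. The table of the 2-cell and 8-cell stages has 30676 rows with gene symbols or LOC names, and that of the ICM and TE has 27607 rows with Ensembl gene identifiers. Every column was matched to a sample by its name and 0 columns belonged to no sample. An entry of the first table names no gene. It held 0.184% to 0.95% of the counts of a library (highest in Control 8-cell replicate 1, 0.95%, 95% exact interval 0.945 to 0.954) and was left out of library sizes and tests. A RefSeq gene table matched 15974 of 18361 symbols of the first table, 0 LOC names and 0 of the Ensembl identifiers, and was used for older and newer names only. Groups followed the treatment and stage in the sample titles. The labels do not say that replicates came from separate pools of embryos, so p-values measure only the spread between these samples, which may be technical. The 2 Control 2-cell libraries differed far less than other replicate pairs (chi-square per degree of freedom 2.48, against 15.6 to 330.1 in 15 other pairs) but more than counting noise allows. They were kept as 2 replicates, and a fit with their counts summed into 1 was added after the data were seen.

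Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each table was fitted by itself with 1 coefficient per group, TMM library factors, the filterByExpr filter (minimum count 10, minimum total count 15) and the robust quasi-likelihood test of edgeR, which left 16149 and 14128 genes. All groups of a table shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05, and all tests are 2-sided. The planned comparisons were METTL7A against Control at each stage and lineage, 8-cell against 2-cell and TE against ICM in Control, and the differences of the METTL7A effect between stages and between lineages. The comparisons between stages and between lineages in METTL7A-injected embryos were added after the data were seen. CPM values use TMM-scaled library sizes. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts it is a ratio with an exact 95% counting interval. Both divide the counts of a group by its summed TMM-scaled library sizes. Single-library shares carry exact Clopper-Pearson intervals. These intervals and floors cover counting error only.

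The 18 gene lists were written before the data were examined, as were the comparisons, most alternative settings and the rule for named genes. The lists were antioxidant defence, nuclear oxidative phosphorylation, mitochondrial genome transcripts, integrated stress and unfolded protein response, apoptosis and p53 targets, heat shock, embryonic genome activation, maternal oocyte transcripts, ICM and epiblast, hypoblast and TE markers, ribosomal proteins, cholesterol synthesis, lipid droplets and fatty acids, the m6A machinery, interferon response, cell cycle, and cumulus and somatic cell markers. None of the 13 mitochondrial genome transcripts was among the gene names used, so that list was not analysed here and 17 were tested. Some lists share members, such as SESN2, TFAP2C and KLF17. Lists were tested with camera on log2 CPM (prior count 3) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. With an estimated correlation 0 lists were called in any comparison. The estimates came from few libraries per group and ran from 0.0242 for apoptosis to 0.867 for oxidative phosphorylation, against the preset 0.01. If the true correlations are that high, p-values with the preset value are too small. In Control 8-cell against 2-cell the estimated version missed ribosomal proteins, where 79 of 80 genes rose. A missing call with it is therefore no evidence against a change. List medians use fitted values, and placing members with 0 counts in a whole group at their bound is stated where it moved a median. A further list of steroidogenic granulosa and luteal genes was written after the data were seen.

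Named genes were chosen by a fixed rule. Per treatment comparison these were METTL7A, the 8 largest rises and 8 largest falls past the threshold with a gene symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups' CPM, and up to 4 members of each list with the smallest adjusted p under 0.05. With 2 libraries against 2, chance alone gives no overlap in 33.3% of genes. A list without such a member could be illustrated by its 2 members of highest level. Control stage comparisons used 6 rises and 6 falls and 5 of the lists. Genes outside the rule are said to have been chosen after their values were seen. A gene that the rule takes at the 8-cell stage is not reported here.

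Alternatives were DESeq2 size factors, the DESeq2 Wald test, no low-count filter, a mean of at least 50 counts, fits of the 2 compared groups only, the replicate number as a block, each library left out in turn, the METTL7A entry left out, a fold of at least 2, and for lists an estimated correlation and fry. Added after the data were seen were the summed Control 2-cell libraries, a fit to genes with at least 1 CPM in every 2-cell library, and removal of the trend of the fold change on expression level (span 0.3) in the ICM and TE. Where leaving out a library left 1 sample in a group, that sample is assumed to vary like the other groups.

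Depth was 15781017 to 20737404 counts per library in the first table and 7261807 to 13781538 in the second. A count of 0 in a single library of the second table allows up to 0.206 to 0.479 CPM. The tests were checked on simulated counts with the real genes, means and library sizes and 200 changed genes, all drawn from those at 5 CPM or more. In these edgeR recovered 46% of 4-fold and 2% of 2-fold changes for METTL7A at the 2-cell stage, 35% and 1% at the 8-cell stage, 94% and 39% in the ICM, 89% and 26% in the TE, and 93% and 25% for TE against ICM in Control. These ran on 15767, 15691, 13599, 13693 and 13772 genes. Of the edgeR calls 2 of 50 were false at the 2-cell stage and 8 of 44 at the 8-cell stage. In the ICM 11 of 144 were false, in the TE 5 of 120 and for TE against ICM 8 of 126. With DESeq2 the false calls were 15 of 101, 47 of 133, 35 of 187, 30 of 180 and 25 of 165 in the same order. The simulated spread of each gene was edgeR's own estimate, the same in all groups, and genes were drawn independently. The real groups differed in spread, so these rates need not hold for the real tests, and the setting may favour edgeR.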

Results

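RNA-seq was performed on bovine embryos that had received METTL7A mRNA or vehicle as zygotes, and libraries were made at the 2-cell stage, at the 8-cell stage and from the 2 cell populations of the blastocyst. These are the inner cell mass (ICM), which gives rise to the embryo proper, and the trophectoderm (TE), the outer layer that contributes to the placenta. METTL7A, also named TMT1A, is a membrane-bound methyltransferase of thiol compounds found at the endoplasmic reticulum and on lipid droplets. The 20 libraries fell into 8 groups, with 2 libraries per group at the 2-cell and 8-cell stages and 3 per group in the ICM and TE. Vehicle-injected groups are called Control below. No group received another mRNA, so the METTL7A effect below cannot be told apart from that of injecting mRNA as such. Total gene counts ranged from 15781017 to 20737404 per library at the 2-cell and 8-cell stages, where 17914 to 20242 genes were detected, and from 7261807 to 13781538 in the ICM and TE, where 15817 to 19894 genes were detected. In the 2-cell and 8-cell table the first principal component held 77.9% of the variance and parted the stages, and the second held 18.2% and parted the treatments at the 8-cell stage. In the ICM and TE table the first component held 41.2% and parted METTL7A-injected from Control libraries. Levels are given in CPM, the read count scaled to library size, as mean ± SD over the libraries of a group, with n = 2 at the 2-cell and 8-cell stages and n = 3 in the ICM and TE.

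The injected transcript was present in every METTL7A-injected library of the 2-cell and 8-cell stages at 1.61% to 5.23% of the counts. METTL7A reached 45280 ± 3450 CPM in injected 2-cell embryos against 16.6 ± 3.44 CPM in Control, a log2 fold change of 11.41 (SE 0.653, adjusted p = 0.000184). At the 8-cell stage it stood at 28430 ± 13700 CPM against 7.46 ± 0.153 CPM, a log2 fold change of 11.89 (SE 0.665, adjusted p = 0.00015). Per library, METTL7A took 5.23% of all counts (95% exact interval 5.222 to 5.244) and 4.68% (4.673 to 4.691) in the injected 2-cell libraries, and 1.61% (1.602 to 1.615) and 2.74% (2.735 to 2.75) in the injected 8-cell libraries. The Control libraries held 462 and 328 METTL7A counts at the 2-cell stage and 131 and 129 at the 8-cell stage. From the 2-cell to the 8-cell stage the METTL7A level differed by a log2 fold change of -1.16 in Control embryos (adjusted p = 0.0506) and of -0.67 in injected embryos (adjusted p = 0.235), neither past the threshold. Leaving out either Control 8-cell library brought the Control value past it, at adjusted p = 0.0499 without replicate 1 and 0.0337 without replicate 2. Counts of the unnamed locus LOC781439 moved with METTL7A, at 2345 ± 323 CPM against 0.764 ± 0.205 CPM in 2-cell embryos and 3285 ± 1540 CPM against 1.18 ± 0.402 CPM in 8-cell embryos (log2 fold changes 11.57 and 11.43, adjusted p = 0.000184 and 0.00015). This locus was singled out after its values were seen, and whether it shares reads with METTL7A as a near-identical copy is uncertain. The paralogue METTL7B, also chosen after its values were seen, had 0 counts in all 8 libraries. Gene names were not matched in the ICM and TE table, so the injected transcript was not followed there.

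**Figure D1:**
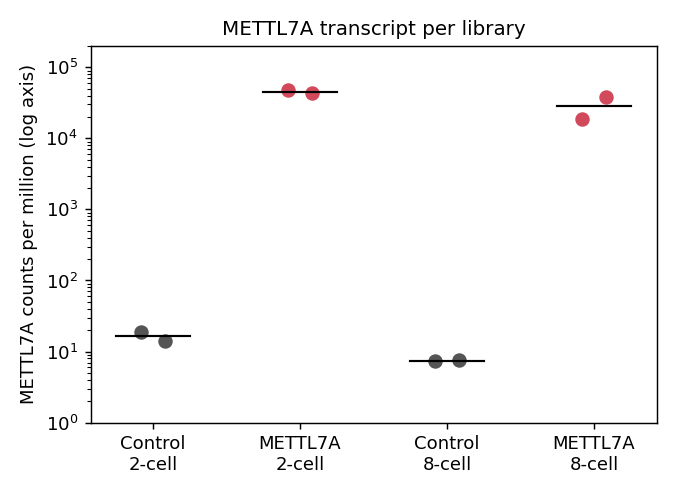
METTL7A level per library in CPM on a log axis, with 1 point per library, a bar at the mean of each group, Control in grey and METTL7A-injected in red. Injected libraries sit at 18750 to 47720 CPM and Control libraries at 7.36 to 19.1 CPM.

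With edgeR over all groups, only the injected transcript and a locus that moves with it passed the test in 2-cell embryos. Of 16149 genes tested, 2 were higher in METTL7A-injected embryos and 0 were lower, and the 2 were METTL7A itself and LOC781439. None of the 17 gene lists tested was called by camera with all libraries, and 1 was called lower without METTL7A 2-cell replicate 1. Among the lists were the antioxidant genes, the group nearest to the oxidative stress named in the title of the study, where 0 of 50 tested members passed. FTL, the light chain of the iron store ferritin, stood at 702.7 ± 339 CPM in injected and 556 ± 19.6 CPM in Control embryos (log2 fold change 0.34, adjusted p = 0.931). Maternal transcripts such as BTG4, which takes part in the clearance of maternal mRNA, stood at 7928 ± 1820 against 5354 ± 289 CPM (0.57, adjusted p = 0.843). CCNB1, which encodes cyclin B1, stood at 2631 ± 109 against 1965 ± 86 CPM (0.42, adjusted p = 0.894). HMGCS1, an enzyme early in cholesterol synthesis, stood at 974.1 ± 45.5 against 809.6 ± 19.8 CPM (0.27, adjusted p = 0.97), and DHX58, a sensor of viral RNA, at 206.6 ± 5.43 against 331.2 ± 0.9 CPM (-0.68, adjusted p = 0.636). With the p-values adjusted over the list alone, 3 list members passed, and these were chosen after their values were seen. Among the 27 integrated stress response genes these were DNAJB9, a chaperone of the endoplasmic reticulum, at 2.95 (1.03 ± 0.147 against 0.128 ± 0.064 CPM) and SESN2, a stress-induced sestrin, at -1.47, and among the 20 genes of the m6A machinery RBM15B, a subunit of the methyltransferase complex, at -1.67. Their adjusted p over all genes was 0.466, 0.479 and 0.474. At an unadjusted p under 0.05, edgeR gave 1196 genes where chance gives 807, and DESeq2 called 158 genes, 31 higher and 127 lower. A fit of the 2-cell groups alone called 1005 genes, 299 higher and 706 lower, and a fit without the low-count filter called 100. The fit over all groups also takes in the spread of the Control 8-cell pair (chi-square per degree of freedom 330.1). That of the 2-cell groups alone leans on the Control 2-cell pair, which differed least of all pairs (2.48). For the lists, the adjusted p was 0.975 in all 17 camera tests, the smallest unadjusted p was 0.352, and fry called 0 lists. In data simulated for this design with edgeR's estimate of the spread, edgeR recovered 46% of 4-fold and 2% of 2-fold changes. Of its calls 2 of 50 were false, and of the DESeq2 calls 15 of 101.

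At the 8-cell stage METTL7A-injected embryos differed from Control in 854 genes, 119 higher and 735 lower. By camera with a preset correlation 8 gene lists were lower in injected embryos, from interferon response (median -3.70) and oxidative phosphorylation (-2.21) to ribosomal proteins (-0.487), and 3 were higher, genome activation, maternal and cell cycle transcripts, with no member past the test. With an estimated correlation 0 of the 11 lists were called (adjusted p = 0.306 to 0.693 with an estimated correlation), and 7 were called without Control replicate 1. The falls of lowest fitted log2 fold change were in genes with many Control counts and 0 counts, or 1, in injected embryos. LTC4S, the synthase of leukotriene C4, had 246.3 ± 295 CPM in Control embryos and was at least 2130-fold lower in injected ones (adjusted p = 0.0204), taking 3 counts over the group as the floor. CRIP1, a small LIM-domain protein, was at least 1200-fold lower (139.1 ± 142 CPM in Control, adjusted p = 0.0129) and MAP1LC3C, an autophagy protein of the LC3 family, at least 968-fold lower (112.5 ± 94.8 CPM, adjusted p = 0.0111). SEMA6D, LGALS3BP, HS6ST2 and TMEM98 were at least 922-fold, 855-fold, 769-fold and 588-fold lower. TMEM176B had 1 count in injected and 12322 counts in Control libraries, a ratio of 9010 with an exact counting interval of 1620 to 356000 (adjusted p = 0.00299). These sizes rest on Control replicate 1, where LTC4S stood at 454.5 CPM against 38.0 CPM in replicate 2. From replicate 2 alone the bounds were 323-fold for LTC4S, 331-fold for CRIP1, 386-fold for MAP1LC3C, 198-fold, 127-fold, 116-fold and 74.3-fold for the next 4, and the ratio of TMEM176B was 4420 (792 to 175000).

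The rises of highest log2 fold change after METTL7A were in genes of low or moderate level. DBNDD1 rose by a log2 fold change of 5.03, from 0.342 ± 0.152 to 11.4 ± 10.4 CPM (adjusted p = 0.0267), and CXCL5, a neutrophil-attracting chemokine, by 4.36, from 1.04 ± 0.601 to 21.5 ± 21.2 CPM (adjusted p = 0.0366). STX19, a syntaxin, rose by 3.39 and AGR2, a disulfide isomerase of the endoplasmic reticulum, by 3.34. The transcription factor IRF4 rose by 2.98, DAW1 by 2.7 and LIX1 by 2.61, the last from 18.3 ± 3.61 to 111.8 ± 92.6 CPM. Of these 7 genes only STX19 stayed past the threshold without Control 8-cell replicate 1.

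**Figure D2:**
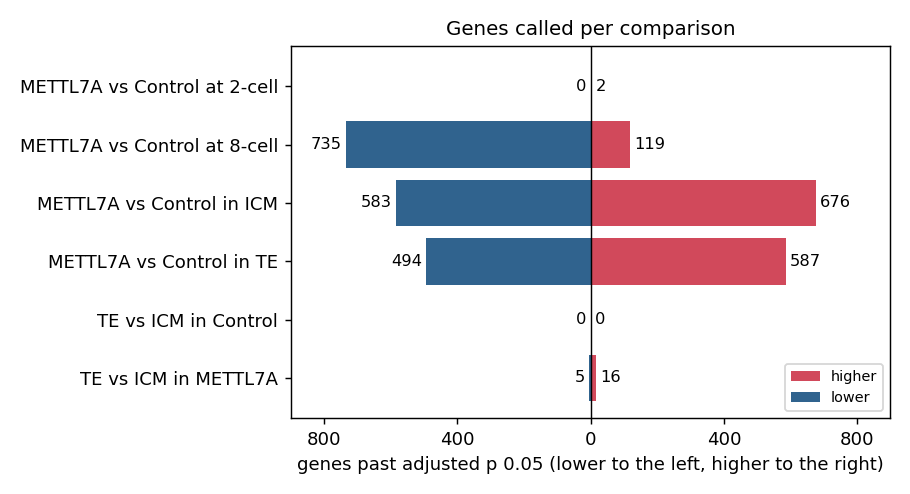
Genes past an adjusted p of 0.05 in 6 comparisons, with the number lower to the left and the number higher to the right of 0. METTL7A against Control gave 2 genes at the 2-cell stage, 854 at the 8-cell stage, 1259 in the ICM and 1081 in the TE, and TE against ICM gave 0 in Control and 21 in METTL7A-injected embryos.

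Interferon response genes had the lowest median of the 17 lists at the 8-cell stage. Of 23 tested, 12 fell, 0 rose and 11 did not pass (18 fell when adjusted over the list alone), with a median log2 fold change of -3.70, or -3.55 with members that had 0 counts in a whole group placed at their bound. IFI6, an interferon-induced mitochondrial protein, fell from 2063 ± 2110 to 0.704 ± 0.0485 CPM (log2 fold change -11.50, adjusted p = 0.00478). OAS1Y, a synthase of the oligoadenylates that activate RNase L, fell from 280.7 ± 240 to 0.153 ± 0.0975 CPM (-10.75, adjusted p = 0.00395), and IFIT5, which binds viral RNA, from 140.7 ± 105 to 2.08 ± 0.926 CPM (-6.07, adjusted p = 0.0072). ISG15, a ubiquitin-like protein, had 3 counts in injected and 4720 in Control libraries, a ratio of 1150 (exact counting interval 393 to 5580), or 402 (137 to 1950) without Control replicate 1. The list was lower by camera (adjusted p = 1.7e-15) and by fry (adjusted p = 0.00455). By camera it was not called with an estimated correlation (adjusted p = 0.306 with an estimated correlation). IFI6 stood at 3556 CPM in Control replicate 1 and 570.2 CPM in replicate 2. Without replicate 1 the list median was -3.42 (adjusted p = 2.42e-16), and without METTL7A replicate 1 it was -6.61 (adjusted p = 5.64e-12).

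Lower values were also found for genes of energy metabolism. Among 76 nuclear genes of oxidative phosphorylation 30 fell, 0 rose and 46 did not pass (58 fell when adjusted over the list alone), with a median of -2.21 (camera adjusted p = 9.96e-17; adjusted p = 0.543 with an estimated correlation). UQCR11, a small subunit of complex III, fell from 153.1 ± 158 to 0.342 ± 0.247 CPM (-8.75, adjusted p = 0.00964), and NDUFS4 of complex I from 265.6 ± 269 to 7.74 ± 5.97 CPM (-5.09, adjusted p = 0.0258). NDUFC2 and NDUFS6 of complex I fell with log2 fold changes of -4.52 and -4.47. The median was -0.763 without Control replicate 1 (adjusted p = 3.69e-10). Of 80 ribosomal protein genes 1 fell, RPL18 (-2.77, adjusted p = 0.0415), and 79 did not pass (0 when adjusted over the list alone). The ribosomal list was lower, with a median of -0.487 (camera adjusted p = 0.00296; adjusted p = 0.693 with an estimated correlation). It turned to 0.12 without Control replicate 1 (adjusted p = 0.41) and was -0.92 without Control replicate 2, and the call was lost without METTL7A replicate 1 (-0.38, adjusted p = 0.121).

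Some lipid genes fell as well. In cholesterol synthesis 12 of 23 genes fell, 0 rose and 11 did not pass (21 fell when adjusted over the list alone), with a median of -2.44 (camera adjusted p = 8.87e-11; adjusted p = 0.543 with an estimated correlation). TM7SF2, MVD and SC5D, enzymes of the pathway, fell (-5.53, -4.89 and -3.60). Among 28 genes of lipid droplets and fatty acids 3 fell, 0 rose and 25 did not pass (9 fell and 1 rose when adjusted over the list alone), with a median of -1.11 (camera adjusted p = 2.22e-05; adjusted p = 0.543 with an estimated correlation). SCD, which introduces a double bond into saturated fatty acids, fell from 381.5 ± 419 to 0.591 ± 0.836 CPM (-9.26, adjusted p = 0.016), ACSL4 from 365.8 ± 367 to 25.2 ± 13.2 CPM (-3.86, adjusted p = 0.0323) and HADHB, an enzyme of beta-oxidation, fell as well (-2.04). Without Control replicate 1 the medians were -1.15 (adjusted p = 1.6e-08) and -0.471 (adjusted p = 0.00827), and HADHB lost its call. The second was -1.67 without Control replicate 2.

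A minority of antioxidant genes fell and none rose. Of 50 tested, 9 fell, 0 rose and 41 did not pass (18 fell when adjusted over the list alone), with a median of -1.06 (camera adjusted p = 3.57e-06; adjusted p = 0.543 with an estimated correlation). GPX1, the cytosolic glutathione peroxidase, fell from 687 ± 831 to 5.78 ± 1.18 CPM (-6.89, adjusted p = 0.0194). MT2A, a metallothionein, GPX7 and GSTO1, a glutathione transferase, fell as well (-5.70, -4.88 and -3.94). The median was -0.275 without Control replicate 1 (adjusted p = 0.00827), and MT2A, GPX7 and GSTO1 then lost their calls.

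Markers of cumulus and other somatic cells, included to show RNA of cells other than blastomeres, differed in where they were found. Of the 15 tested, 8 stood at 1 CPM or more in every 2-cell library and 11 in every injected 8-cell library, and STAR, HAS2 and FBN1, chosen here after their values were seen, stood higher in the Control 2-cell than in the Control 8-cell libraries, at 213.6 and 216.1 against 33.2 and 34.9 CPM for STAR. In the list 4 fell, 0 rose and 11 did not pass (8 fell when adjusted over the list alone), with a median of -2.0 (camera adjusted p = 0.000449; adjusted p = 0.361 with an estimated correlation; fry adjusted p = 0.0102). LUM, which encodes the matrix proteoglycan lumican, fell from 2725 ± 2910 to 1.38 ± 0.178 CPM (-10.94, adjusted p = 0.0146), and POSTN, the matrix protein periostin, from 153.9 ± 47.6 to 1.73 ± 0.986 CPM (-6.48, adjusted p = 0.00478). The collagen genes COL3A1 and COL1A2 fell with log2 fold changes of -6.88 and -4.55. LUM stood at 4782 CPM in Control replicate 1 and 667.2 CPM in replicate 2, and at 0.784 CPM or less in the 2-cell libraries. Without Control replicate 1 the list median was -0.575 (adjusted p = 0.00827), and COL1A2 lost its call. The 735 lower genes together held 14.29% (95% exact interval 14.27 to 14.3) of the counts of Control 8-cell replicate 1, 2.52% (2.513 to 2.528) of replicate 2, 0.425% and 0.382% in the injected 8-cell libraries and 0.644% to 0.756% at the 2-cell stage.

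Lineage markers moved in both directions. Among 17 hypoblast markers 5 fell, 1 rose and 11 did not pass (10 fell and 2 rose when adjusted over the list alone), with a median of -1.63 (camera adjusted p = 0.00296; adjusted p = 0.543 with an estimated correlation). SPARC, a collagen-binding matrix protein, fell from 1221 ± 1310 to 3.35 ± 0.353 CPM (-8.51, adjusted p = 0.0116), APOA1, an apolipoprotein, from 797.5 ± 945 to 0.236 ± 0.021 CPM (-11.68, adjusted p = 0.0148) and the laminin gene LAMA1 by 5.36, whereas CTSV, a lysosomal protease, rose from 135.1 ± 1.11 to 335.4 ± 40.2 CPM (1.31, adjusted p = 0.0326). SPARC stood at 2144 CPM and APOA1 at 1466 CPM in Control replicate 1, against 298.1 and 129.5 CPM in replicate 2. The hypoblast median was -0.684 without Control replicate 1 (adjusted p = 0.0151), and LAMA1 lost its call. Of 17 ICM and epiblast markers 2 fell, CDH2 (-6.89) and SPP1 (-3.29), and 15 did not pass (2 fell and 2 rose when adjusted over the list alone). That list was not called (adjusted p = 0.367) and its median of 0.655 and mean of -0.381 differed in sign. Among 18 TE markers 2 fell and 16 did not pass (2 fell when adjusted over the list alone), again with no call (adjusted p = 0.606) and a median of 0.23 against a mean of -0.645. The 2 were the keratin gene KRT8 (-4.85) and CYP11A1, the enzyme that opens steroid hormone synthesis, with 1 count in injected and 9100 counts in Control libraries, a ratio of 6650 (exact counting interval 1190 to 263000), or 1260 (226 to 49900) without Control replicate 1. SPP1 and KRT8 lost their calls without Control replicate 1.

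**Figure D3:**
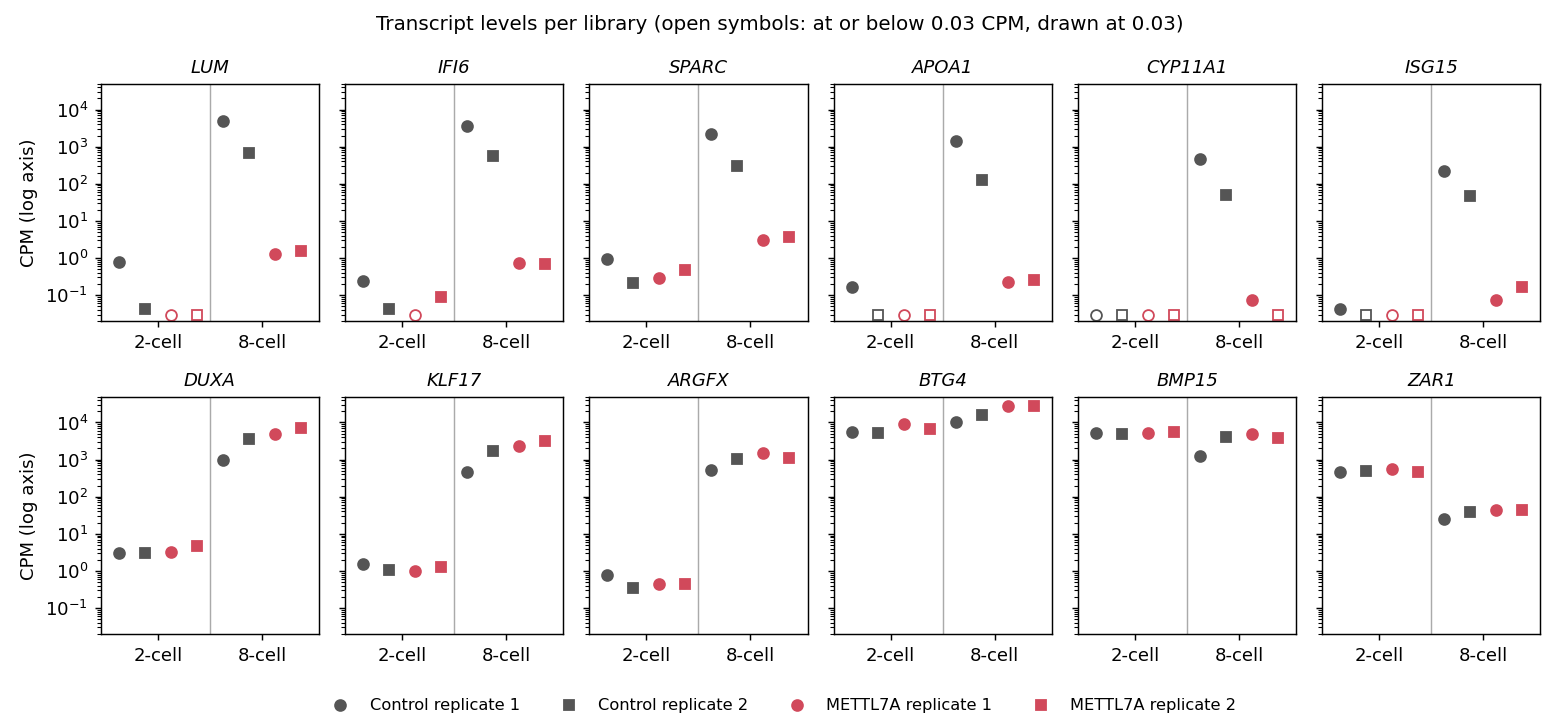
Levels of 12 transcripts in the 8 libraries of the 2-cell and 8-cell stages, in CPM on a log axis, with circles for replicate 1, squares for replicate 2, Control in grey and METTL7A-injected in red. LUM, IFI6, SPARC, APOA1, CYP11A1 and ISG15 were high in the Control 8-cell libraries alone, more so in replicate 1, and DUXA and KLF17 were lowest in that library among the 8-cell libraries.

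Transcripts of the embryo's own genome activation stood higher in injected 8-cell embryos, without a single member past the test. The median of 17 genome activation genes was 0.853 (0 rose and 0 fell, also when adjusted over the list alone; camera adjusted p = 0.00798; adjusted p = 0.543 with an estimated correlation). DUXA and KLF17, transcription factors first transcribed around the time of genome activation, stood at 6033 ± 1680 against 2295 ± 1840 CPM and at 2731 ± 540 against 1073 ± 860 CPM (adjusted p = 0.148 for both). The call was lost without Control replicate 1 (median 0.695, adjusted p = 0.0711) and without METTL7A replicate 2 (0.47, adjusted p = 0.114). For 32 maternal oocyte transcripts the median was 0.562 (0 rose and 0 fell, also when adjusted over the list alone; camera adjusted p = 0.00153; adjusted p = 0.595 with an estimated correlation). BTG4 stood at 27610 ± 635 against 13020 ± 4170 CPM (adjusted p = 0.118) and BMP15, an oocyte growth factor, at 4314 ± 778 against 2612 ± 1930 CPM (adjusted p = 0.371). For 24 cell cycle genes it was 0.535 (0 rose and 0 fell, also when adjusted over the list alone; camera adjusted p = 0.00688; adjusted p = 0.595 with an estimated correlation), with CCNB1 at 2777 ± 163 against 1539 ± 774 CPM (adjusted p = 0.191). Both calls were lost without Control replicate 1, where the medians were 0.17 (adjusted p = 0.326) and 0.291 (adjusted p = 0.0891). Without Control replicate 2 the medians of the 3 lists were 1.51, 1.27 and 1.03, all still called. DUXA stood at 993.6 CPM, KLF17 at 464.9 CPM and BMP15 at 1249 CPM in Control replicate 1, against 3597, 1681 and 3974 CPM in replicate 2.

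Genes of mRNA modification and of stress responses showed single members past the test at the 8-cell stage. Among 20 genes of the m6A machinery, which writes, removes and reads the methyl mark on mRNA, 2 rose, 0 fell and 18 did not pass (3 rose when adjusted over the list alone). The reader YTHDF3 rose from 137.5 ± 46.6 to 416.7 ± 81.7 CPM (1.60, adjusted p = 0.0338) and RBM15, a subunit of the methyltransferase complex, from 21 ± 0.294 to 67.6 ± 17.3 CPM (1.68, adjusted p = 0.0343), while the list was not called (median 0.531, adjusted p = 0.0635). Of 27 integrated stress and unfolded protein response genes DDIT3, a pro-apoptotic transcription factor, rose from 402.2 ± 75.5 to 1013 ± 164 CPM (1.33, adjusted p = 0.0426), HERPUD1, which takes part in the degradation of misfolded proteins, fell by 3.57 (adjusted p = 0.0426) and 25 did not pass (2 rose and 4 fell when adjusted over the list alone). Among 16 heat shock genes the small chaperones HSPB1 and CRYAB fell (-4.17 and -6.74) and 14 did not pass (3 fell and 1 rose when adjusted over the list alone). None of 26 apoptosis and p53 genes passed (0 when adjusted over the list alone), and CCNG1, a p53 target, stood at 423.6 ± 81.3 against 226.4 ± 63.2 CPM (adjusted p = 0.108). These 3 lists were not called (adjusted p = 0.367, 0.421 and 0.367). RBM15, DDIT3, HERPUD1 and CRYAB lost their calls without Control replicate 1.

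The 8-cell counts rest on few libraries, and so does the excess of lower over higher genes. It remained without Control 8-cell replicate 1 but nearly disappeared without Control replicate 2. Without Control 8-cell replicate 1 the test called 370 genes, 56 higher and 314 lower, of which 345 were among the 854, and without Control replicate 2 it called 7129. Leaving out either METTL7A 8-cell library left 2 genes, and DESeq2 called 2374 genes, 668 higher and 1706 lower. Fitted to the 11499 genes with at least 1 CPM in every 2-cell library, a choice made after the data were seen, edgeR called 4 genes, 1 higher and 3 lower, although 80 of the 119 and 337 of the 735 genes were among them, and the hypoblast and cumulus lists were then not called (median 0.125, adjusted p = 0.924, and -0.0482, adjusted p = 0.362).

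**Figure D4:**
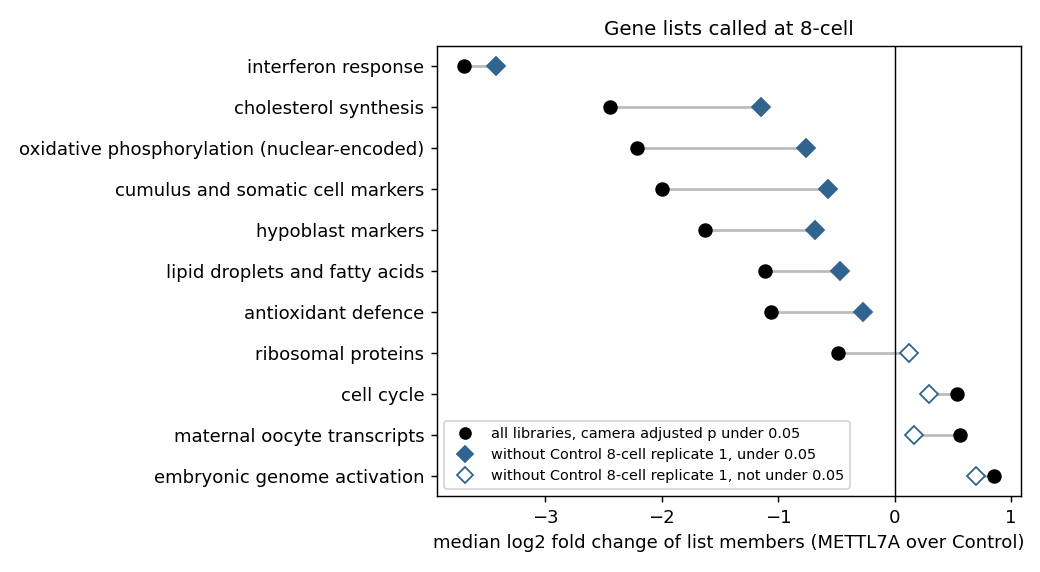
Median log2 fold change (METTL7A over Control, 8-cell stage) of the 11 gene lists called by camera, with black circles for all libraries and diamonds for the fit without Control 8-cell replicate 1, filled where the adjusted p stayed under 0.05. Interferon response genes lie lowest in both, at -3.70 and -3.42, and 4 of the 11 lists have an open diamond.

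Between the 2-cell and 8-cell stages Control embryos changed 8516 of 16149 genes, 4834 higher and 3682 lower at the 8-cell stage. Most genes of genome activation, ribosomal proteins and oxidative phosphorylation rose, and 18 of 32 maternal transcripts fell. In the genome activation list 14 of 17 genes rose, 1 fell and 2 did not pass (the same numbers when adjusted over the list alone), with a median of 5.36 (camera adjusted p = 7.03e-05; adjusted p = 0.722 with an estimated correlation). ARGFX, a homeobox gene of the preimplantation embryo, rose from 0.565 ± 0.31 to 780.5 ± 357 CPM (10.41, adjusted p = 3.95e-05), DUXA from 3.06 ± 0.106 to 2295 ± 1840 CPM (9.55) and the translation factor EIF1AX from 10.5 ± 0.0842 to 431.3 ± 57.1 CPM (5.36). Of 32 maternal oocyte transcripts 18 fell, 2 rose and 12 did not pass (18 and 2 when adjusted over the list alone), with a median of -1.17 (camera adjusted p = 7.03e-05; adjusted p = 0.722 with an estimated correlation). NLRP2 and NLRP5, of the subcortical maternal complex family, fell (-4.09 and -4.41), and ZAR1, an RNA-binding protein of the oocyte, fell from 483.7 ± 10.3 to 31.4 ± 9.67 CPM (-3.94, adjusted p = 8.23e-05). Among ribosomal protein genes 79 of 80 rose (79 when adjusted over the list alone) with a median of 4.76 (camera adjusted p = 6.69e-25), and among oxidative phosphorylation genes 72 of 76 rose and 0 fell (73 rose when adjusted over the list alone) with a median of 3.94 (camera adjusted p = 3.89e-14). Neither was called with an estimated correlation (adjusted p = 0.722 with an estimated correlation for both), although most of their genes passed singly. The estimates were 0.774 and 0.867. Without Control 8-cell replicate 1 the oxidative phosphorylation median was 2.57 and the maternal one -0.778, and without replicate 2 the maternal one was -2.08, all still called.

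Markers of the later lineages were already measurable in the Control 8-cell libraries. For some of them RNA of cells other than blastomeres stays possible, and 13 of the 17 tested hypoblast markers stood higher in replicate 1 than in replicate 2. Among genes that rose, picked here after their values were seen, APOA1 stood at 1466 and 129.5 CPM and KRT8 at 476 and 33.4 CPM in replicates 1 and 2. CTSV (134.3 and 135.9 CPM) and TFAP2C (36.4 and 117.3 CPM) were not higher in replicate 1. ZFP42 and NANOG, pluripotency factors, had 2 counts each in the 2-cell libraries, and the ratios were 3150 (exact counting interval 873 to 26100) and 378 (104 to 3130). Of the ICM and epiblast list 9 of 17 rose and 3 fell, of the hypoblast list 8 of 17 rose and 2 fell, and of the TE list 9 of 18 rose and 5 fell (9 and 3, 9 and 2, and 9 and 5 when adjusted over the list alone). These 3 lists were not called by camera (adjusted p = 0.169, 0.0783 and 0.46), whereas fry, which does not compare a list with other genes, called all 3 higher (adjusted p = 0.00203, 0.0131 and 0.00531). TFAP2C, a transcription factor of the trophectoderm, rose by 9.72, PRDM14 by 6.64 and CTSV by 4.25, while the water channel gene AQP3 fell by 4.41. The 6 rises of highest fitted log2 fold change were genes without a count at the 2-cell stage, CYP11A1, TAGLN, POSTN, SERPINB10, HSD11B1 and ADAMTS1, at least 4120-fold, 3040-fold, 2420-fold, 2470-fold, 2090-fold and 1970-fold higher. These bounds depend on Control 8-cell replicate 1, and without it they were 782-fold, 597-fold, 2960-fold, 38-fold, 182-fold and 523-fold. CYP11A1 stood at 463.6 CPM in Control replicate 1 and 49.5 CPM in replicate 2, and SERPINB10 at 304 and 2.41 CPM. The falls of lowest log2 fold change included LLGL2, a regulator of cell polarity, from 435.9 ± 0.588 to 11.5 ± 5.96 CPM (-5.24), and FLNC, an actin cross-linker, from 220.5 ± 12.6 to 6.47 ± 2.88 CPM (-5.09). Interferon response genes rose in 16 of 23 cases and fell in 3 (median 5.12, or 4.51 with members at their bound, camera adjusted p = 0.00156), antioxidant genes rose in 29 of 50 and fell in 5 (1.85, adjusted p = 0.0164) and cholesterol genes rose in 14 of 23 and fell in 2 (2.24, adjusted p = 0.0387). Adjusted over the list alone these were 16 and 3, 29 and 5, and 15 and 2. With an estimated correlation they had adjusted p = 0.722, 0.722 and 0.723. Without Control 8-cell replicate 1 the antioxidant and cholesterol calls were lost (0.866, adjusted p = 0.154, and 0.875, adjusted p = 0.278). Leaving out Control 2-cell replicate 1 or 2 lowered the number of genes to 5127 or 5174. Size factors in place of TMM factors shifted the median of all genes by 0.11 in this comparison, and log2 values here are relative to the TMM scale.

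The test of whether the METTL7A effect differed between the 8-cell and 2-cell stages called 2 genes, both with a lower effect at the 8-cell stage. STC1, which encodes the calcium-regulating hormone stanniocalcin, had a log2 effect of 3.37 at the 2-cell stage (adjusted p = 0.269) and of -4.63 at the 8-cell stage (adjusted p = 0.0072), a difference of -8.00 (SE 0.698, adjusted p = 0.0155). The unnamed locus LOC100139670, singled out after its values were seen, had a difference of -11.47 (SE 1.24, adjusted p = 0.0464). Both calls were lost without either Control 2-cell library or either METTL7A 8-cell library, and that of LOC100139670 also without either METTL7A 2-cell library. DESeq2 called 917 genes, and 2588 genes had an unadjusted p under 0.05 with edgeR.

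In the blastocyst METTL7A-injected and Control embryos differed in both lineages. In the ICM 1259 of 14128 genes passed, 676 higher and 583 lower, and in the TE 1081 passed, 587 higher and 494 lower. The lineages shared 239 higher and 176 lower genes, where 28.1 and 20.4 would be shared by independent lists, and 0 genes were called in opposite directions. Across all genes the log2 effects in the ICM and TE had a Pearson r of 0.629 and a Spearman rho of 0.55, and 69% of genes had the same sign. The libraries of the lineages are separate, with no shared control libraries, but the embryos and their handling may be shared. Genes are not independent replicates. Both lists also come from 1 fit with a shared estimate of each gene's spread. Genes of small spread are likelier to be called in both, so independent lists are no even reference. This table gives gene identifiers with no names and none of the 27607 matched a symbol in the reference table used, so the gene lists were not tested here. The identifiers given are those of highest and lowest fitted log2 fold change in each lineage among a filtered set. These were past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the groups' CPM. The order does not hold for genes with 0 counts in a group, as in the first of them. In the ICM ENSBTAG00000047998 had 454 counts in injected and 0 in Control libraries (10.6 ± 15.8 CPM, adjusted p = 0.0456), and ENSBTAG00000010284 fell from 13.5 ± 19.3 to 0.663 ± 0.685 CPM (-4.41, adjusted p = 0.0407). In the TE ENSBTAG00000046155 rose from 0.54 ± 0.271 to 54.6 ± 28.1 CPM (6.63, adjusted p = 2.07e-05), and ENSBTAG00000008871 fell from 40.9 ± 16.5 to 2.44 ± 0.367 CPM (-4.06, adjusted p = 0.0356). Of the identifiers given here, only ENSBTAG00000046155 kept its call whichever library was left out. ENSBTAG00000008871 lost it without any of the 6 TE libraries (adjusted p = 0.073 to 0.139) and ENSBTAG00000047998 without any Control ICM library (0.0812 to 0.121) or METTL7A ICM replicate 2 (0.0506). ENSBTAG00000010284 stood at -1.88 without Control ICM replicate 1 (adjusted p = 0.192) and lost its call without METTL7A ICM replicates 2 and 3 (0.127 and 0.0795).

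The fold changes in the blastocyst varied with the level of the gene. In the ICM the median log2 fold change was 0.561 among genes under 1 CPM and -0.307 among those over 100 CPM, and in the TE 0.46 and -0.15. METTL7A-injected libraries held 18702 to 19894 detected genes and Control libraries 15817 to 18294. The ICM count was 512 without Control replicate 1, 457 without Control replicate 2 and 353 without METTL7A replicate 2. The TE count was 363, 314 and 453 without Control replicates 1, 2 and 3, and 421 and 297 without METTL7A replicates 1 and 2. In the 2-group fits the ICM count was 124 and the TE count 2492, and DESeq2 called 2113 and 1760 genes.

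**Figure D5:**
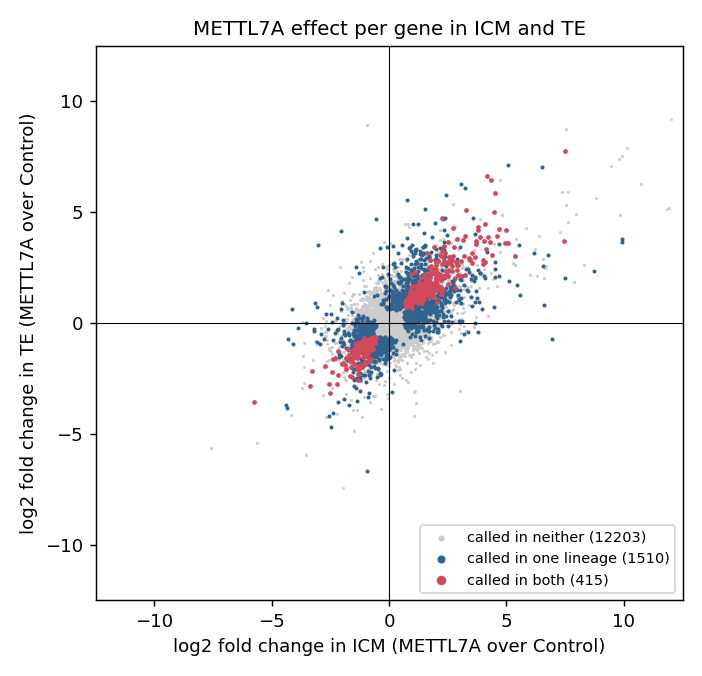
Log2 fold change (METTL7A over Control) of each gene in the ICM on the horizontal axis and in the TE on the vertical axis, with genes called in both lineages in red, in 1 lineage in blue and in neither in grey. The 415 genes called in both lie in the upper right and lower left parts of the plot, 239 and 176 of them.

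Comparison of TE with ICM in Control embryos, which asks what separates the first lineages of the embryo, called 0 of 14128 genes with edgeR. Its smallest adjusted p was 0.0782, 2479 genes had an unadjusted p under 0.05 where chance gives 706, and DESeq2 called 496 genes. Leaving out Control ICM replicate 3 gave 405 genes, 81 higher and 324 lower in the TE. The same comparison in METTL7A-injected embryos, added after the data were seen, called 21 genes, 16 higher and 5 lower in the TE. The METTL7A effect did not differ between TE and ICM for any gene with edgeR, where the smallest adjusted p was 0.0922, 1170 genes had an unadjusted p under 0.05 and DESeq2 called 33. In data simulated for the Control comparison with edgeR's estimate of the spread, edgeR recovered 93% of 4-fold and 25% of 2-fold changes. Of its calls 8 of 126 were false, and of the DESeq2 calls 25 of 165.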

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

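The tests on the Control 8-cell libraries in this part, the genes named there and the list of steroidogenic granulosa and luteal genes were chosen after the results were seen, whereas the tests of the difference between the stages and the other lists were planned.

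STC1 and LOC100139670 are given here because the METTL7A effect at the 8-cell stage differed from that at the 2-cell stage in a test of the difference itself. For STC1 the difference was -8.00 (SE 0.698, edgeR adjusted p = 0.0155). STC1 stood at 23.4 and 57.0 CPM in the injected 2-cell libraries against 3.96 and 3.81 CPM in Control, and at 7.68 and 6.53 CPM in the injected 8-cell libraries against 221.4 and 130 CPM in Control. For LOC100139670 the difference was -11.47 (SE 1.24, adjusted p = 0.0464). It stood at 129.9 and 46.7 CPM in the Control 8-cell libraries and at 0.797 CPM or less in the other 6, so the size of its fitted difference depends on very few counts.

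The same test called 12 of the 17 gene lists by camera with the preset correlation, 4 with a higher and 8 with a lower METTL7A effect at the 8-cell stage, and 0 of them with an estimated correlation (adjusted p = 0.362 to 0.825 with an estimated correlation). The higher ones were genome activation (median difference 0.992), cell cycle (0.698), m6A machinery (0.595) and maternal transcripts (0.585), with adjusted p = 0.0383, 0.0116, 0.0381 and 0.0046. The lower ones were interferon response (-3.20, adjusted p = 4.87e-14), hypoblast markers (-2.91, 0.00538), cumulus and somatic cell markers (-2.51, 0.000533), oxidative phosphorylation (-2.22, 1.29e-15), cholesterol synthesis (-2.16, 4.88e-09), antioxidant defence (-0.918, 1.31e-05), lipid droplets and fatty acids (-0.904, 0.000533) and ribosomal proteins (-0.495, 0.0381). Fry called 1, the interferon list (adjusted p = 0.0201). Without Control 8-cell replicate 1 the number of lists called was 5, with medians of -2.54 for interferon response, -1.08 for cholesterol synthesis, -0.883 for cumulus and somatic cell markers, -0.849 for oxidative phosphorylation and -0.262 for antioxidant defence. Those not called then were hypoblast markers (-0.741), lipid droplets and fatty acids (-0.252), ribosomal proteins (0.209), genome activation (0.659), cell cycle (0.345), m6A machinery (0.39) and maternal transcripts (0.22), with adjusted p = 0.0504 to 0.334. Without Control 8-cell replicate 2 the m6A call was lost (0.995, adjusted p = 0.0581), and the medians were 1.53 for genome activation, 1.27 for maternal transcripts, 1.11 for cell cycle, -1.39 for antioxidant defence and -0.857 for ribosomal proteins. Without METTL7A 2-cell replicate 1 genome activation (0.758, adjusted p = 0.109), m6A machinery (0.421, 0.0765) and ribosomal proteins (-0.144, 0.75) lost their calls, as the first 2 did without METTL7A 8-cell replicate 2 (0.642, 0.203, and 0.418, 0.092) and the last without Control 2-cell replicate 1 (-0.464, 0.189) or METTL7A 8-cell replicate 1 (-0.439, 0.32). The cumulus median was -0.54 and -0.927 without METTL7A 2-cell replicates 1 and 2 and -1.55 without METTL7A 8-cell replicate 2, where the cell cycle median was 0.401, and the interferon median was -5.28 without METTL7A 8-cell replicate 1.

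Of the 735 genes called lower in injected than in Control 8-cell embryos, 247 (33.6%, against 7.12% of all tested genes) were under 1 CPM in the other 6 libraries. All 735 stood higher in Control replicate 2 than in both injected 8-cell libraries. They stood higher in Control replicate 1 than in replicate 2 in 728 cases, with a median ratio of 5.11 where all tested genes gave 0.975. As they were called from these same values, such a ratio is partly fixed by their choice, and all tested genes are no even reference. RNA of cells other than blastomeres, carried unequally into the Control libraries, is a candidate explanation that needs such a ratio: LUM (4782 and 667.2 CPM in replicates 1 and 2), TIMP1 (1068 and 197.3) and OXT (524.5 and 15.3) followed it, but 9 of the 15 tested cumulus and somatic cell markers, a list fixed before, stood higher in replicate 1, and 8 of the 15 were also at 1 CPM or more in every 2-cell library. The 17 steroidogenic granulosa and luteal genes, of which 14 stood higher in replicate 1 and 11 fell, were listed after such genes had been seen, so their fall is no test of it. No cell type is settled by this, since POSTN (120.2 and 187.6 CPM) went the other way and CYP19A1 (0.674 and 1.82 CPM) and STAR (33.2 and 34.9 CPM) were not above their 2-cell levels. For more advanced embryos in replicate 1 the prediction was higher genome activation genes and lower maternal transcripts than in replicate 2. The 32 maternal transcripts stood at 0.511 of replicate 2, but the 14 activation genes stood at 0.504, with 3 of 14 higher, so only the maternal part was met. More advanced embryos stay undecided, as embryos past the peak of activation would also have lower activation genes, a reading adopted after the result was seen. Dilution by other RNA could give both values. Lower levels in the injected embryos themselves also stay open, because 305 of the 735 genes were still called lower without replicate 1, and with 2 Control libraries these explanations cannot be told apart.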

How the results depend on the processing

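The summed Control 2-cell libraries, the fits to genes present at the 2-cell stage, the removal of the trend on expression level and the lineage comparison in METTL7A-injected embryos were chosen after the results were seen, and the other alternatives were planned. In the ICM and TE a count of 0 in a library allows up to 0.206 to 0.479 CPM, so lower levels were not detectable at this depth. With 2 libraries per group at the 2-cell and 8-cell stages, leaving 1 out leaves a single sample that is assumed to vary like the other groups, and the number of genes called then moved by large factors. METTL7A itself kept its rise in each alternative run, with a log2 fold change of 11.2 to 11.64 at the 2-cell stage and 11.3 to 12.32 at the 8-cell stage over the fits without 1 library.

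In the simulated data a larger share of DESeq2 than of edgeR calls was false in each comparison run. At the 8-cell stage these were 47 of 133 against 8 of 44. The simulated spread was edgeR's own estimate, the same in all groups, so these shares cannot decide between the tools on the real data. With the DESeq2 Wald test the number of genes was 158 at the 2-cell stage (2 by edgeR), 2374 at the 8-cell stage (854), 917 for the difference between stages (2), 2113 in the ICM (1259), 1760 in the TE (1081), 496 for TE against ICM in Control (0) and 33 for the difference between lineages (0). Without the low-count filter these were 100, 2767 and 1354 for the first 3, and 248 and 17 for the last 2. Fits of the 2 compared groups only gave 1005 genes at the 2-cell stage, 283 at the 8-cell stage, 124 in the ICM and 2492 in the TE. A fold of at least 2 left 819 genes in the ICM by its construction. For the difference between stages the number was 1 with DESeq2 size factors, 1 with a mean of at least 50 counts, 1 with METTL7A left out and 1 among genes present at the 2-cell stage, and at the 2-cell stage it was 1 with METTL7A left out, which removes a called gene. With the Control 2-cell libraries summed, which leaves fewer samples, it was 5404 for Control 8-cell against 2-cell (8516) and 0 for the difference between stages. Among genes present at the 2-cell stage 4 were called at the 8-cell stage. TE against ICM gave 21 genes in METTL7A-injected embryos. Except where the construction shows it, the cause was not tested.

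With an estimated correlation 0 lists were called at the 8-cell stage (11 with the preset value), 0 in Control 8-cell against 2-cell (7) and 0 for the difference between stages (12). Fry called 2, 11 and 1 lists, of which 2, 5 and 1 were among those that camera called.

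Over the fits without 1 library the number of genes ranged from 2 to 2 at the 2-cell stage, 2 to 7129 at the 8-cell stage, 5127 to 10759 in Control 8-cell against 2-cell, 0 to 4568 for the difference between stages, 353 to 1522 in the ICM, 297 to 884 in the TE, 0 to 405 for TE against ICM in Control and 0 to 2 for the difference between lineages. The extremes were 2 without METTL7A 8-cell replicate 1 or 2 and 7129 and 4568 without Control 8-cell replicate 2. The number of lists ranged from 0 to 1, 7 to 11, 5 to 10 and 5 to 12 in the first 4 of these comparisons.

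In 5 cases the direction turned, taken for lists from the direction of camera and not from the median. The ribosomal list ranged from -0.92 to 0.12 at the 8-cell stage and from -0.857 to 0.209 for the difference between stages, both positive without Control 8-cell replicate 1. FTL at the 2-cell stage ranged from -0.23 to 0.75 and was negative without METTL7A 2-cell replicate 1, and the difference between stages for METTL7A ranged from -0.14 to 0.87 and was negative without METTL7A 8-cell replicate 2, neither past the threshold in any fit. The hypoblast list, with fewer genes left when only those present at the 2-cell stage were tested, had a median difference between stages of -0.162 (-2.91 over all genes) while camera put it in the other direction (adjusted p = 0.94). Its median for METTL7A against Control at the 8-cell stage turned positive in the same fit, as given above, which this count by camera direction leaves out. The cause was not tested in the first 4 cases.

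For 87 called values of named genes the alternatives gave 866 values on the same side of the threshold and 201 no longer past it, of which 55 of 56 each came without METTL7A 8-cell replicate 1 and without replicate 2, 26 of 85 with the 2 compared groups only, 19 of 86 without Control 8-cell replicate 1 and 19 of 21 among genes present at the 2-cell stage. For 30 called lists 260 values stayed and 78 did not, of which 30 were with an estimated correlation, 22 with fry and 11 without Control 8-cell replicate 1. The identifiers picked by rule in the ICM and TE, not all of them given above, had 63 and 38. Of values not past the threshold 175 stayed so and 23 passed. The fit without METTL7A was not run for the ICM and TE, where the transcript was not matched.

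Replicate numbers paired the samples weakly at most. Deviations of same-numbered libraries from their group means had r of 0.00432 to 0.0586 within treatment at the 2-cell and 8-cell stages and -0.000559 to 0.168 between ICM and TE, with 1 of 6 over 0.1. Within treatment, ICM and TE libraries of different numbers had r of -0.164 to 0.0879, with a median of -0.0298 against 0.0834 for the same number. In METTL7A-injected embryos the same-numbered pairs had 0.0983, 0.0973 and 0.0696, and the other pairs 0.00373 or less. In Control the values of both kinds of pairs overlapped. With the replicate number as a block the difference between stages had 24 genes, and the other numbers of genes stayed within 1.5 times, at 1083 at the 8-cell stage, 1179 in the ICM and 1029 in the TE.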

Other observations

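The stage comparison in METTL7A-injected embryos, and the tests of sequencing depth, of the level trend as the whole cause, of METTL7A injection and of the position of Control ICM replicate 3, were chosen after the results were seen. The test that takes out the trend on expression level was written down after that trend had been seen and before its removal was run, and the other splits of the libraries were planned.

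METTL7A-injected embryos also passed through genome activation between the 2-cell and 8-cell stages. Of 16149 genes 6496 changed, 3733 higher and 2763 lower at the 8-cell stage (edgeR). In the genome activation list 14 of 17 genes rose and 1 fell, with a median of 6.07 (camera adjusted p = 1.36e-06; adjusted p = 0.914 with an estimated correlation), among them ARGFX (11.47), KLF17 (11.22) and DUXA (10.54). The rises of highest fitted log2 fold change included the histone gene HIST1H2BJ, at least 2040-fold higher, BECN2, a relative of the autophagy gene beclin, from 0.145 ± 0.0447 to 1386 ± 539 CPM (13.12, adjusted p = 2.24e-05), and DPPA4, a pluripotency-associated gene, at least 743-fold higher. NANOG was at least 390-fold higher, and ZFP42 had a ratio of 7520 (exact counting interval 2080 to 62100). Of 32 maternal transcripts 13 fell and 5 rose (median -0.991, camera adjusted p = 0.00724; adjusted p = 0.914 with an estimated correlation), with ASTL, an oocyte protease, lower by a log2 fold change of -3.74. MYD88, an adaptor of innate immune receptors, fell by 4.65 and UBASH3A from 134.4 ± 47.1 to 6.01 ± 1.09 CPM (-4.48, adjusted p = 6.38e-05).

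Ribosomal protein genes rose in 78 of 80 cases in injected embryos (median 4.38, camera adjusted p = 1.29e-26; adjusted p = 0.914 with an estimated correlation), and oxidative phosphorylation genes in 35 of 76 with 2 lower (1.53, adjusted p = 5.88e-05), where Control embryos had 72 of 76. Genes of lipid droplets and fatty acids fell in 9 of 28 cases and rose in 2 (-1.43, adjusted p = 0.00608). Neither these nor the oxidative phosphorylation genes were called with an estimated correlation (adjusted p = 0.914 for each). The interferon list had 2 higher and 5 lower of 23 and was not called (adjusted p = 0.738), nor was the cholesterol list, with 2 higher and 6 lower of 23 (adjusted p = 0.232). The steroidogenic list had 1 higher and 1 lower gene of 17 and was not called either. In the cumulus and somatic list 5 of 15 genes were higher and 2 lower, again without a call (camera adjusted p = 0.805). The 5 were TNFAIP6, COL1A1, LUM, DCN and POSTN, so rises of such markers were not confined to Control embryos. The treatments shared 3006 of the genes higher at the 8-cell stage, 62.2% of those in Control and 80.5% of those in injected embryos. Independent lists would share 1117. Of the lower genes 2151 were shared, where independent lists would share 630. The lists of both treatments come from 1 fit with a shared estimate of each gene's spread, so independent lists are no even reference.

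In the ICM and TE METTL7A-injected libraries held more detected genes and higher values of low genes than Control libraries. Depth alone is argued against, since after thinning to 7261807 counts the lowest injected library still held 18206 genes and the highest Control library 17595, a gap of 611. A trend of the fold change on expression level is argued against as the whole cause, since 904 genes in the ICM and 938 in the TE were called with it taken out, 785 and 827 of them among those called before, but it stays open for a part, as 269 of the 415 genes called the same way in both lineages (64.8%) remained so. METTL7A injection also stays open, as the log2 effects of the lineages had a Pearson r of 0.595 across genes with the trend taken out. These effects were measured in separate libraries. A difference in how injected and Control blastocysts were processed could give the same. Control embryos received no mRNA, so METTL7A and mRNA injection as such are not separated. The real grouping gave 1259 genes in the ICM and 1081 in the TE, matched by 1 of the 10 splits in each, the real one, with 13 and 0 genes in the highest other split, and 10 splits are too few for a share under 0.05.

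Between Control ICM and TE edgeR called 0 genes (2479 at an unadjusted p under 0.05, and 496 by DESeq2), and 405 without Control ICM replicate 3. On the genes called without it, that library lay at a median position of 0.606. On this scale the other ICM libraries stand at 0 and the TE at 1. The position could come from TE cells in that sample. The METTL7A-injected ICM libraries, which took no part in choosing the genes, lay at 0.519 to 0.792. The METTL7A-injected TE libraries took no part either and lay at 0.862, 1.03 and 0.901, near the TE end. A pull to the middle by the choice of genes alone is therefore not shown, and TE cells in replicate 3 stay undecided. The highest number of genes called by another split of these 6 libraries was 0, so exchanging libraries between the lineages gave no more genes. This cannot decide on a swap of labels as the cause of the low count, since every split includes Control ICM replicate 3. A true grouping with that library in it could also call 0 genes. A wrong label on a single library was not tried. As the real split called 0 too, all 10 of the 10 splits reach it by definition and say nothing of chance.

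The lineage comparison in METTL7A-injected embryos gave 21 genes, reached by 1 of the 10 splits, the real one, with 1 gene in the highest other split, again too few splits for a share under 0.05. For the difference of the METTL7A effect between TE and ICM, edgeR called 0 genes (1170 at an unadjusted p under 0.05, and 33 by DESeq2). As the count is 0, all 100 of 100 assignments of lineage within treatment reach it by definition, with 1 gene in the highest other, and this says nothing of chance.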
